A study of Mus musculus with 2 samples.

How the data were processed

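Total RNA of 2 clones of mouse E14 embryonic stem (ES) cells that overexpress Klf5, a zinc finger transcription factor, was hybridised to 2 Affymetrix Mouse Genome arrays, 1 array per clone. Per the labels, the cells were grown undifferentiated in serum medium with LIF (leukaemia inhibitory factor, which sustains ES cell self-renewal), RNA was taken with a column kit and the target was labelled with biotin. Both arrays form 1 group with n = 2, and the clone numbers in the sample titles were used as replicate numbers. The labels name 2 clones but do not say whether they were grown or hybridised on the same day. The study compares these clones with wild-type ES clones of an earlier series; those wild-type arrays were not analysed here, so nothing below is a change caused by Klf5.

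The authors deposited 1 log2 signal per probe set and array, processed with Transcriptome Analysis Console per the submitters' processing notes. The background correction, the summarisation, the normalization and whether other arrays were normalized with these are not given in the sources used here. The log base is not stated either; base 2 was taken from the range of the deposited values, 2.21 to 14.38, and every fold below rests on it. The medians of the 2 columns were 5.27 and 5.18. The values carry 2 decimals and were used as deposited. They hold no probe-level intensities, so detection calls could not be computed and the number of arrays limits the precision.

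The table held 45037 probe sets. In the platform annotation used here 34945 of them had 1 gene symbol, 932 had several and 9160 are unnamed here; genes were named from the first kind alone, 18193 genes in all. Entrez identifiers of 34741 of these probe sets matched the gene table of assembly GRCm38.p6, which changed 0 symbols and gave chromosomes and gene lengths (the genomic span). No build is named for the files, so no coordinates are printed. A gene with several probe sets was represented by the one with the highest mean of both arrays.

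Because the affinities of probe sets differ, no signal was ranked against another probe set's as abundance. A background level was set per array as the 95th percentile of 68 probe sets of 49 genes restricted to adult tissues (caseins, crystallins, digestive enzymes, lymphocyte receptors and the like, 56 listed): 6.40 in clone 1 and 6.09 in clone 2. Because these levels differ, a gene can pass in clone 2 alone through its lower level: of 673 genes above background in clone 2 alone, 397 had a signal there no higher than the level of clone 1, and 92 had a higher signal in clone 1. Differences are clone 2 minus clone 1 on the log2 scale. Where a probe set was above background in 1 clone alone, the difference is printed with a bound, "at least N-fold", in which the dimmer clone's signal was raised to its background level.

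With 1 array per clone there are no residual degrees of freedom between the clones. No p-value was computed, and a difference of at least 2-fold with the higher clone above background was used as a fixed rule of size. For each of 30 gene lists and for each chromosome the median difference of the genes above background in at least 1 clone was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. Percentiles below 2.5 or above 97.5 are called outside the random range; they describe these 2 arrays and not the genotype. The lists, the background genes and the naming rule were fixed before the data were examined. The rule named all Klf5 probe sets, and per list the members with the largest absolute difference and with the highest mean signal, up to 4. It also named the 12 genes with the largest difference in each direction whose other probe sets above background, if any, went the same way. Among those genes only Emsy and Rbm26 had another probe set above background. The rest met this condition by default, each resting on a single probe set. Genes of a list that had no probe set with a single symbol were left out.

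The procedure was checked on simulated differences for 10010 genes, drawn from normal distributions centred on 0 with the observed SD at each level of signal. Of genes planted at 1.5 on the log2 scale, 95.0% were found at 2-fold or more, of genes planted at 1.0, 43.0%, and of unplanted genes 0.122%. The draws leave out the observed median of 0.09, any heavier tails and the background condition, so 0.122% is not a rate of false calls in these data. Of unplanted lists of 16 genes, 4.0% fell outside the random range. The alternatives were 3 other normalizations (median, quantile, loess with a span of 0.3), background at the 90th or 99th percentile, from sensory receptor probe sets or none, each clone alone, the mean over a gene's probe sets, 1 probe set per gene, and the omission of probe sets that may bind several transcripts. Chosen after the data were seen were the background without Mylpf, the higher background asked of both clones, the dim clone raised to its background, signal above background asked in both clones, random lists matched also on gene length (5 length bins within each signal bin, genes with a length), the Klf and Sp list without Klf5, and the imprinted list without 6 genes of 2 clusters. On differences simulated with a trend along gene length, 17.5% of lists of 40 short genes fell outside the range matched on signal and 7.5% outside that matched on length too. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.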

Results

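Gene expression was profiled on arrays in 2 clones of Klf5-overexpressing mouse E14 ES cells kept undifferentiated with serum and LIF, 1 array per clone. The clones were measured to be set against wild-type ES cells, which were not analysed here; the comparisons that these data allow are what both clones express above background and how far they differ from each other. Of 45037 probe sets, 16315 (36.2%) were above background in clone 1, 17838 (39.6%) in clone 2 and 16185 (35.9%) in both. These cover 9271 genes above background in both clones and 10010 in at least 1, of which 63.2% had a higher signal in clone 2. The median difference was 0.09 over the probe sets above background in at least 1 clone and -0.03 over all probe sets. Quantile normalization moved the former to 0, so the share depends on the scale of the arrays and on the filter. Across all probe sets the signals of the clones correlated with r = 0.990 (across probe sets, which are not replicates). The SD of the difference between clones was 0.287 on the log2 scale over the probe sets above background in at least 1 clone, 0.356 in the dimmest of 4 signal bands and 0.219 in the brightest.

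Klf5, the overexpressed gene, was read by 3 probe sets, of which 2 were above background in both clones. The brightest gave 11.61 in clone 1 and 12.25 in clone 2, a mean of 11.93 ± 0.45 (SD, n = 2). Another gave 6.97 and 7.26. The third gave 4.81 and 4.77, which is not above background in either clone. Klf5 was thus 1.56-fold higher in clone 2 by the brightest probe set and 1.22-fold higher by the other. Among the 4491 probe sets of the same signal band, 57 (1.27%) differed by at least as much as the brightest, 50 of them higher in clone 2. Whether a probe set lies within the transgene is not given in the sources used here, and without wild-type arrays the signals do not measure the extent of overexpression.

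The measured genes of the naive and general pluripotency lists, not all of them transcription factors, were above background throughout. All 15 measured naive pluripotency factors passed it in both clones, among them Nanog at 12.21 in clone 1 and 12.49 in clone 2, Zfp42 (Rex1) at 12.69 and 12.77, Klf4 at 11.16 and 11.67, and Nr0b1 at 8.84 and 9.34. Of these 15 genes, 13 were higher in clone 2, and 0 differed 2-fold. The median difference of 0.19 lay at percentile 96.9 of random lists, and outside the random range under quantile or loess normalization, with background at the 99th percentile, with the mean over a gene's probe sets, or among random lists matched on gene length too (chosen after the data were seen). It lay inside with background at the 90th percentile (percentile 96.7) or no filter (percentile 97.0). All 15 measured general pluripotency factors were also above background in both clones. They included Dppa5a at 14.15 and 14.06, Trim28, a co-repressor of retroviral elements, at 13.26 and 13.21, L1td1 at 12.15 and 12.47, and Lin28a, which represses let-7 maturation, at 9.76 and 9.29. Their median difference was 0.02, at percentile 41.0. Pou5f1 (12.26 and 12.43) and Sox2 (12.39 and 12.55) lay outside the naming rule and were chosen after their values were seen.

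Of 14 measured formative and primed epiblast factors, 7 were above background in both clones and Pou3f1 (6.36 and 6.60, chosen after its values were seen) in clone 2 alone. Otx2, a transcription factor of the formative epiblast and anterior neural tissue, was 7.27 in clone 1 and 8.71 in clone 2, a difference of 2.71-fold and the one member to differ 2-fold. The de novo methyltransferase Dnmt3b was 11.74 and 11.79, Nodal 10.73 and 10.56, and Lefty2 7.51 and 7.89. The list's median of 0.09 lay at percentile 51.7. In the Klf and Sp family 14 of 19 measured genes were above background in both clones, including Klf9 at 12.18 and 12.17, and Klf12 in clone 2 alone (5.88 and 6.20, chosen after its values were seen). Sp3 was 7.75 and 8.57, 1.77-fold higher in clone 2. The family's median difference of 0.23 lay at percentile 97.6, equal to the upper end of the random range, and inside the range with background at the 90th percentile or no filter. Klf5 itself is a member, and in the main setting the call depends on it. Without Klf5 the other 14 genes had a median of 0.185 at percentile 89.5, inside the range (chosen after the data were seen). The list without Klf5 was placed in that setting alone. With Klf5 the list lay at percentile 99.6 with background at the 99th percentile and 99.9 with the mean over a gene's probe sets. Of 9 measured genes of the 2-cell-like state, 5 were above background in both clones, among them Tcstv1 (7.21 and 7.61), Arg2 (7.01 and 7.38), Eif1a (10.91 and 11.02) and Usp17la (10.18 and 9.83). Tcstv3, chosen after its values were seen, passed in clone 2 alone (6.10 and 6.40). The Zscan4 genes that mark this state share a probe set with several symbols, which was not used here. The list's median of 0.205 lay at percentile 81.6.

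Markers of lineages other than the epiblast were above background in part. Over all genes, 9271 of 18193 measured passed in both clones. Of 15 measured neurectoderm genes 1 passed in both clones, Nes (6.90 and 7.14), and Tubb3 passed in clone 2 alone (6.35 and 6.79); their median of 0.34 lay at percentile 89.7. Of 15 mesoderm and primitive streak genes Mesp2 passed in both (6.90 and 7.05). Mesp1, a regulator of early cardiac mesoderm, was 7.30 in clone 1 and not above background in clone 2 (6.04), at least 2.32-fold higher in clone 1. The median over these 2 genes, -0.555, lay at percentile 0.265, and the list was inside the range with background at the 90th percentile or no filter. Blood and endothelial markers passed for 1 of 12 genes, Gata1 (7.09 and 7.06), with a difference of -0.03 at percentile 30.5. Of 18 fibroblast feeder markers 4 passed in both clones, namely Vim (11.07 and 11.31), Fn1 (10.45 and 10.45) and, chosen after their values were seen, Thy1 (7.54 and 7.66) and Pdgfrb (7.33 and 7.16); none of these is specific to fibroblasts. Acta2 passed in clone 2 alone (5.99 and 6.35), and the collagens Col1a1 (4.68 and 4.09) and Col3a1 (4.31 and 3.61), chosen after their values were seen, were not above background. The median of 0.12 lay at percentile 56.5.

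Extraembryonic markers were also above background in part. The trophoblast and primitive endoderm counts are close to the share over all genes (9271 of 18193 in both clones), so they do not set these lists apart. Of 20 measured trophectoderm and trophoblast genes 10 passed in both clones, among them Tfap2c (10.04 and 10.00), Krt8 (9.29 and 9.54), Eomes (8.24 and 8.60) and Rhox9 (7.63 and 7.20). Chosen after their values were seen, Tead4 passed in clone 2 alone (6.12 and 6.27) and Cdx2 was not above background (5.38 and 4.89). The list's median of -0.04 lay at percentile 7.14. Of 20 primitive endoderm genes 12 passed in both clones and 3 in 1 clone. The basement membrane genes Sparc (11.07 and 11.56) and Col4a1 (10.12 and 10.53) were among the former. Pdgfra (5.65 and 6.21) and Sox17 (6.31 and 6.81) passed in clone 2 alone, Pdgfra at a signal under the clone 1 level of 6.40. Chosen after their values were seen, Gata6 (6.53 and 6.28) and Hnf4a (7.42 and 6.93) passed in both clones and were lower in clone 2. Gata4, Sox7 and Foxa2 passed in neither clone. Ttr, chosen after its values were seen, passed in clone 1 alone (6.50 and 6.06). The median of 0.12 lay at percentile 60.1. Of 15 germ cell and meiosis genes 12 passed in both clones, including Rhox5 (11.84 and 11.63), Tex19.1 (10.24 and 10.17) and the germ cell helicase Ddx4 (8.08 and 8.61), and the synaptonemal gene Sycp1 in clone 2 alone (5.77 and 6.41); the median of 0.05 lay at percentile 29.0. These lineage counts move with the background level: from sensory receptor probe sets it gave 6 mesoderm, 3 neurectoderm, 7 fibroblast, 15 trophoblast and 17 primitive endoderm genes in both clones, and from the 99th percentile 0, 0, 2, 4 and 8. Background genes without Mylpf, whose signal was well above the background level, gave 3, 2, 4, 11 and 14 (chosen after the data were seen).

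Feedback and target genes of the signalling pathways were compared between the clones as lists. All 10 BMP and SMAD response genes above background were so in both clones and 8 were higher in clone 2, with a median difference of 0.35 against a random range of -0.075 to 0.28 (percentile 99.7). Id4 was 6.81 in clone 1 and 7.36 in clone 2, the inhibitory Smad7 9.64 and 10.11, Bmp4 10.96 and 11.30, and Skil, lower in clone 2, 10.53 and 10.33. Of 10 FGF and ERK response genes 9 were higher in clone 2, with a median of 0.28 against a random range of -0.075 to 0.26 (percentile 98.7). The immediate early factor Egr1 was 7.12 and 7.73, Phlda1 8.86 and 9.43, Etv5 10.97 and 11.25, and Ier2 9.86 and 10.08. In neither list did a member differ 2-fold. LIF and STAT3 response genes were above background for 13 of 14, among them Sgk1 (11.90 and 11.94), Pim3 (11.76 and 11.52), Pim1 (9.98 and 9.41) and Lifr (9.02 and 9.54); the median of 0.03 lay at percentile 24.8. With the mean over a gene's probe sets the LIF list had a median of -0.055 at percentile 2.00, outside the range and in the other direction. WNT response genes passed for 2 of 10 in both clones, Axin2 (7.12 and 7.05) and Notum (7.14 and 7.18), and Znrf3 passed in clone 2 alone (6.25 and 6.70), with a median of 0.04 at percentile 42.6. Across the 29 lists other than the background genes, 4 medians lay outside the random range, those of the BMP, FGF, mesoderm and, through Klf5, Klf and Sp lists, where 1.45 would by chance if the lists were independent. Without a background filter or with it at the 90th percentile 2 lists lay outside, the BMP and FGF lists. The FGF list lay inside with background at the 99th percentile or with the mean over a gene's probe sets. The BMP list lay outside under the 6 alternatives of normalization, background and probe sets that can move a percentile. Among random lists matched on gene length too (chosen after the data were seen), the BMP list also lay outside (percentile 99.9). Quantile and loess normalization lowered the medians of all lists. They turned those of the LIF, WNT, germ cell, cell cycle, glycolysis, interferon and constitutive lists below 0, with these lists inside the range.

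**Figure D1:**
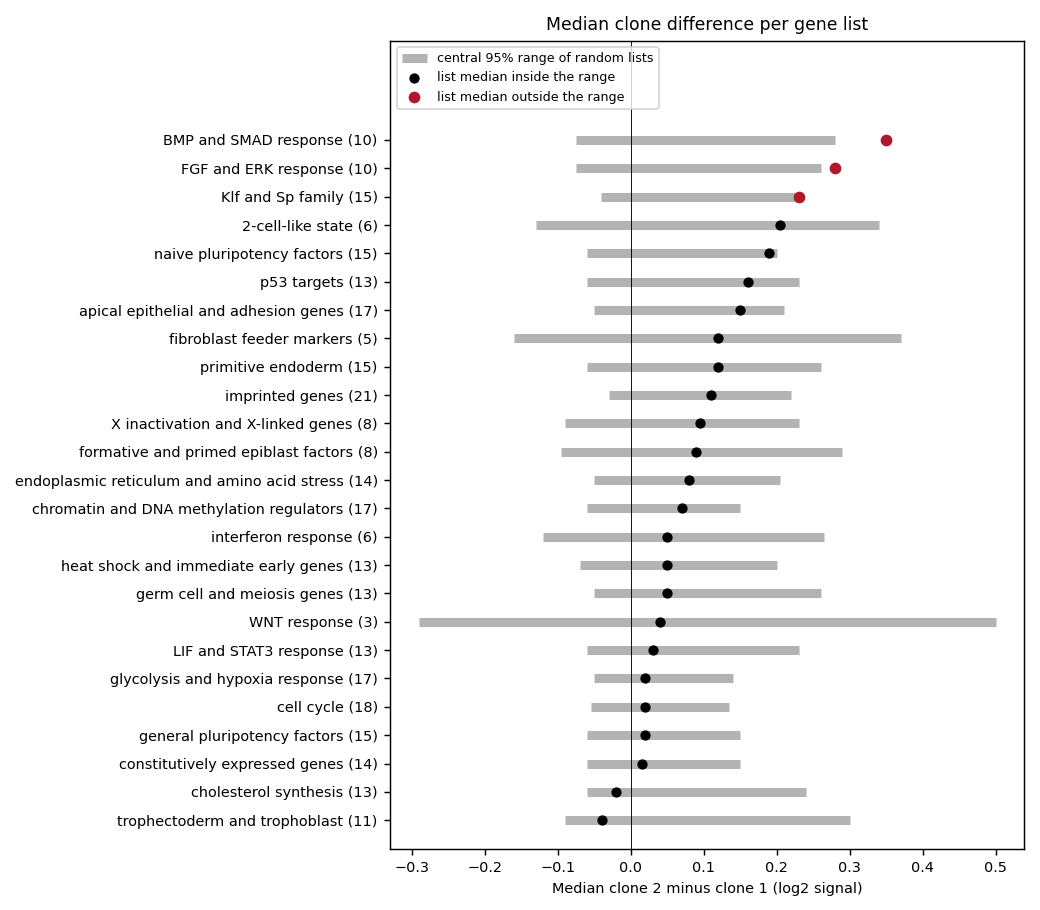
Median difference between the clones (clone 2 minus clone 1, log2 signal, horizontal axis) for each gene list with at least 3 genes above background other than the background genes, the number of genes in parentheses; grey bars are the central 95% range of random lists matched on size and signal. The BMP and SMAD response at 0.35, the FGF and ERK response at 0.28 and the Klf and Sp family at 0.23 are drawn in red.

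The remaining programmes differed little between the clones. The 18 cell cycle genes above background in both included Pcna (13.34 and 13.25), Mcm5 (12.86 and 13.01), Bub1 (11.60 and 11.92) and Aurkb (9.65 and 10.13), with a median of 0.02 (percentile 35.9). Glycolysis and hypoxia genes passed for 17 of 18, among them Pkm (13.35 and 13.42), Slc2a3 (13.30 and 13.40), Pdk1 (11.58 and 11.83) and Ankrd37 (9.00 and 8.69), with a median of 0.02 (percentile 36.2). All 13 cholesterol synthesis genes passed, including Hmgcs1 (11.30 and 11.48), Fdps (11.09 and 11.25), Sqle (9.84 and 10.20) and Mvd (8.42 and 8.19), with a median of -0.02 (percentile 7.59). Of 16 endoplasmic reticulum and amino acid stress genes 14 passed, among them Asns (12.47 and 12.71), Hspa5 (12.05 and 12.10), the amino acid transporter Slc7a5 (9.38 and 9.93) and Dnajb9 (8.65 and 8.97), with a median of 0.08 (percentile 57.1). Heat shock and immediate early genes passed for 13 of 16, including Hsp90aa1 (13.70 and 13.86) and Hspa8 (13.72 and 13.60), with a median of 0.05 (percentile 46.7).

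Interferon response genes passed for 6 of 13, among them Ifitm2 (11.81 and 11.70), Ifitm1 (11.04 and 11.06), Ifitm3 (10.76 and 10.49) and Stat2 (6.84 and 7.09), with a median of 0.05 (percentile 43.6). Of 14 measured p53 targets 13 passed, including Ccng1 (11.42 and 11.54), Trp53inp1 (11.17 and 11.74) and Ei24 (10.07 and 10.54), with a median of 0.16 (percentile 86.3). Chromatin and DNA methylation regulators passed for 17 of 18, among them Kdm1a (12.26 and 12.49), Tet2 (8.77 and 9.17) and the remodeller Chd1 (7.90 and 8.76), with a median of 0.07 (percentile 71.5). All 17 apical epithelial and adhesion genes passed, including E-cadherin, Cdh1 (11.80 and 11.82), Itga6 (11.23 and 11.38), Dsp (9.20 and 8.86) and Esrp1 (8.01 and 8.41), with a median of 0.15 (percentile 85.2). The 14 constitutively expressed genes, such as Eef1a1 (14.25 and 14.15), Rpl13a (13.91 and 13.97), Ywhaz (12.17 and 12.44) and Gusb (7.94 and 8.38), had a median of 0.015 (percentile 31.7). Of 49 background genes 3 passed in both clones: the muscle light chain Mylpf (10.53 and 10.48), Cela1 (7.10 and 6.95) and Cd3e (6.50 and 6.34). Sftpb passed in clone 1 alone (6.91 and 6.01) and Ckm, chosen after its values were seen, in clone 2 alone (6.21 and 6.13), where the background was lower. With 5 of these genes above background in at least 1 clone, their median was -0.15 (percentile 7.90).

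Among imprinted genes, which are expressed from 1 parental allele, 6 genes of 2 clusters differed between the clones, in opposite directions. Of 25 measured imprinted genes, 18 were above background in both clones and 3 in 1 clone, namely Igf2 and, chosen after their values were seen, Dlk1 (6.06 and 6.38) and Snrpn (6.39 and 6.50). The median difference of those above background, 0.11, lay at percentile 61.0, with 15 higher in clone 2 and 6 in clone 1. Without Meg3, Rian, Mirg, Cdkn1c, Phlda2 and Igf2, the 15 genes left had a mean absolute difference of 0.234, at percentile 64.8 (chosen after the data were seen). Cdkn1c, Phlda2 and Igf2, which are neighbours on distal chromosome 7, were lower in clone 2 by the brightest probe set of each gene, the first 2 of them by 2-fold or more and Igf2 by a bound under 2-fold. The growth inhibitor Cdkn1c was 8.18 in clone 1 and 6.64 in clone 2 (7.41 ± 1.09, SD, n = 2; 2.91-fold). Phlda2, a placental growth regulator, was 9.49 and 8.20 (2.45-fold). Igf2, a fetal growth factor, was 7.03 and 5.64, not above background in clone 2 and so at least 1.92-fold higher in clone 1; its other probe set was not above background. Other named members were Slc38a4 (10.78 and 11.22) and Ube3a (10.90 and 10.93). On chromosome 12 the non-coding transcripts Meg3, Rian and Mirg were higher in clone 2. Meg3 differed by 0.57, 1.10, 1.13 and 1.26 in 4 probe sets above background in both clones, Rian by 0.47 and 0.88 in 2, and Mirg by 0.64 in 1. These 7 had a median of 0.88. Of the probe sets above background in clone 2 alone, 1 of Meg3 was at least 2.09-fold and 1 of Mirg at least 1.77-fold higher in clone 2, and the remaining probe sets of these genes were not above background. Meg3, Rian and Mirg were chosen from the list after their values were seen.

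**Figure D2:**
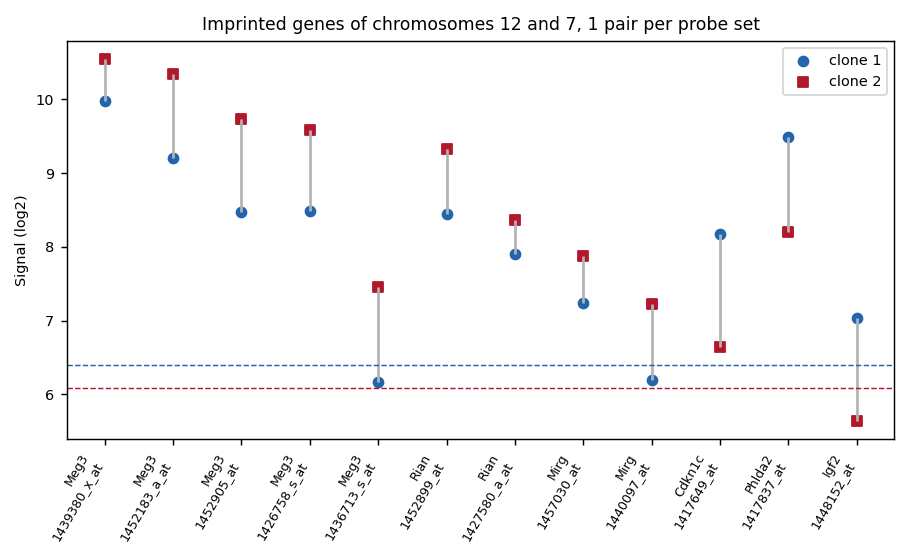
Signal (log2, vertical axis) of each probe set above background in at least 1 clone for 6 imprinted genes; circles are clone 1, squares clone 2, and dashed lines the background levels of 6.40 (clone 1) and 6.09 (clone 2). All 9 probe sets of Meg3, Rian and Mirg lie higher in clone 2, and those of Cdkn1c, Phlda2 and Igf2 lie lower.

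Sex-linked genes were read as a check on the clones. Of 7 measured Y-linked genes Eif2s3y was above background in both clones (7.41 and 7.79) and Sry, by the brighter of its probe sets, in clone 2 alone (6.29 and 6.14, higher in clone 1 but under that array's higher background), with a median of 0.115 (percentile 43.2). Among 10 measured X inactivation and X-linked genes 8 passed, including Pgk1 (13.32 and 13.34), Hprt (11.89 and 11.79), Ogt (10.56 and 11.01) and Xist (8.70 and 8.19 by its brightest probe set, its others not being above background), with a median of 0.095 (percentile 65.9). Whole chromosomes differed little: the medians of the 20 chromosomes ranged from 0.05 to 0.11, against 0.585 for 3 copies over 2. Chromosomes 6 and 7, each at 0.05, lay at percentiles 1.08 and 0.09. Their sign depends on the normalization, since quantile or loess normalization turned both below 0. With the mean over a gene's probe sets chromosome 6 lay inside the range, and chromosome 11 (percentile 1.78) and, at the upper end, chromosome 14 lay outside beside chromosome 7.

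Over all features, the measured signals of 111 probe sets were at least 2-fold higher in clone 2 and those of 19 in clone 1, together 0.724% of the 17968 above background in at least 1 clone. These counts take the dimmer clone's signal as measured, also where it is below background; raised to its background level, it left 68 and 11 (chosen after the data were seen). From the measured signals, quantile normalization gave 76 and 26 (74.5% higher in clone 2, against 85.4%), and without a background filter the order turned, with 199 higher in clone 2 and 348 in clone 1. At 1 probe set per gene the counts were 39 and 12 genes. The genes furthest above in clone 2 were Arid4a, a chromatin-binding subunit of a histone deacetylase complex (6.57 and 8.34, 7.46 ± 1.25, SD, n = 2; 3.41-fold), AI987944 (6.21 and 7.71, at least 2.48-fold), Otx2 (above), Emsy (7.16 and 8.52, 2.57-fold), the ubiquitin ligase Rnf216 (7.13 and 8.43, 2.46-fold) and Rbm26 (8.47 and 9.62, 2.22-fold). The lipoprotein receptor Vldlr (5.47 and 6.77), the transporters Slc16a6 (5.41 and 6.95) and Slc15a1 (5.78 and 7.02), Ghdc (5.26 and 6.58), the fucosidase Fuca2 (5.32 and 6.53) and Dmxl1 (5.71 and 6.87) were not above background in clone 1. For these 6 genes the bounds were at least 1.29-, 1.47-, 1.54-, 1.13-, 1.10- and 1.39-fold in that order.

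Beside Cdkn1c, Phlda2, Igf2 and Mesp1, the genes furthest above in clone 1 were the ribosomal protein gene Rpl27a (8.88 and 7.52, 2.57-fold) and Chpf, a chondroitin polymerising factor (7.48 and 6.47, 2.01-fold). Rpl27a belongs to a family with many near-identical copies, and its other probe set with a single symbol was not above background. Ifi203 (6.64 and 5.32), Prelid3a (6.60 and 5.49), AU016916 (6.89 and 5.80), Fam229a (6.45 and 5.37), Cmtm5 (6.57 and 5.56) and Spns3 (6.72 and 5.72) were not above background in clone 2. For these the bounds were at least 1.47-, 1.43-, 1.74-, 1.29-, 1.40- and 1.55-fold in that order. Restricted to probe sets above background in both clones, 61 were 2-fold higher in clone 2 and 10 in clone 1.

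**Figure D3:**
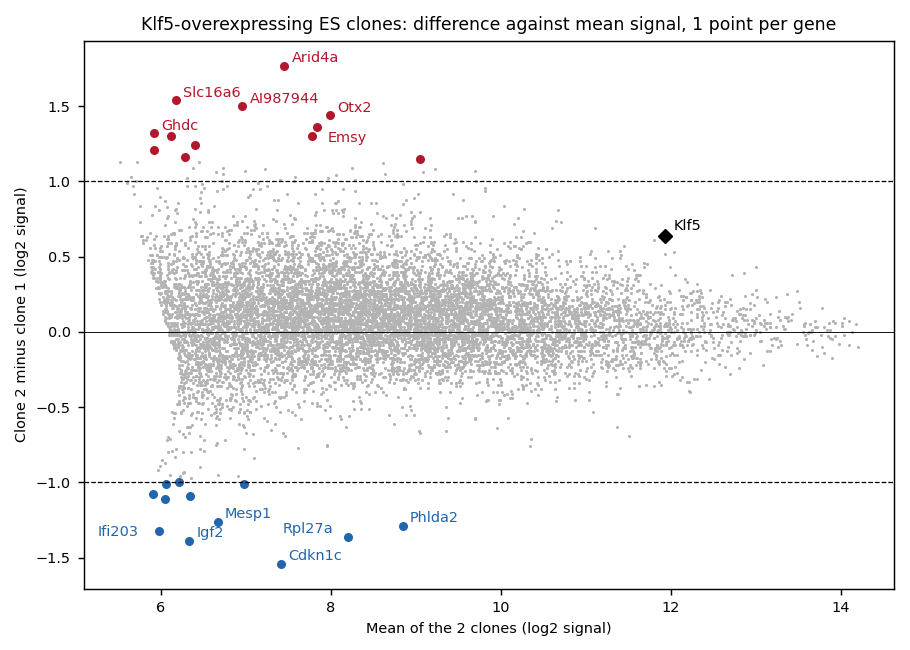
Difference between the clones (clone 2 minus clone 1, log2 signal, vertical axis) against their mean (log2 signal, horizontal axis), 1 grey point for each of the 10010 genes above background in at least 1 clone; dashed lines mark 2-fold, red and blue points the 12 named genes in each direction, and the diamond Klf5. Klf5 lies at 0.64 and Arid4a at 1.77.

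Of the genes whose brightest probe set differed 2-fold, 15 had a second probe set above background, all of them higher in clone 2. It differed in the same direction for 11 of the 15 (73.3%), by 2-fold for 1, with a median of 0.18. Over all 4116 genes with 2 such probe sets, of either direction, the directions matched for 58.4%. Because all 15 were higher in clone 2, as were 63.2% of genes above background, a match in direction says little by itself. Meg3 is not among these 15, since its brightest probe set differed by 0.57 and dimmer ones by 2-fold or more. Emsy had a second probe set at 0.31, and the 4 probe sets of Rbm26 ranged from 0.05 to 1.15. The clones have 1 array each, so these differences carry no p-value and cannot be parted from differences between cultures or hybridisations.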

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

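No paired analysis was possible because the 2 arrays form a single group. Probe sets 2-fold higher in clone 2 and clone 1, 111 and 19 as reported, numbered 134 and 55 with background at the 90th percentile, 47 and 6 at the 99th, 199 and 348 with no filter, and 39 and 12 at 1 probe set per gene. Chosen after seeing the data, raising the dim clone to its background gave 68 and 11, and asking for signal above background in both clones gave 61 and 10. Under the median, quantile and loess normalizations both counts stayed within 1.5 times of those reported (76 to 132 in clone 2 and 15 to 26 in clone 1). The 4 lists outside the random range became 2 at the 90th percentile and 2 with no filter, and 5 among random lists matched on gene length, which left 2 chromosomes outside. Under quantile or loess normalization the naive list joined the 4. At the 99th percentile the naive list lay outside, the FGF list inside, and the mesoderm list gave no value. With the mean over a gene's probe sets the naive and LIF lists joined and the FGF list lay inside. The 2 chromosomes outside became 1 at the 90th percentile and 0 at the 99th or with no filter; with the mean over a gene's probe sets they were 7, 11 and 14. The medians of chromosomes 6 and 7 turned to -0.0325 and -0.0375 under quantile normalization, -0.0243 and -0.0218 under loess, and -0.04 and -0.02 with no filter. These 2 normalizations moved the median of all probe sets above background from 0.09 to 0.00 and 0.0142, so directions are best read relative to that shift. The number of probe sets above background in both clones, 16185, became 8449 at the 99th percentile, where the mesoderm, neurectoderm, blood, WNT and Y-linked lists had no gene left and gave no value; signal over background thus limits what is counted. The SD between clones moved by less than 1.5 times. The brightest Klf5 probe set gave 11.61 with clone 1 alone and 12.25 with clone 2 alone, which is 1.56-fold apart. The share of matching second probe sets ran from 50.0% under quantile normalization to 81.2% with the median of all differences set to 0. All 381 differences of named genes under the 3 normalizations moved by less than the SD between clones (0.287). That limit was wide: the normalizations moved the median of all probe sets above background only from 0.09 to 0.12, 0.00 and 0.0142. The outcome was therefore nearly fixed in advance and says little about single genes. Of the list medians 32 moved beyond their random SD and 174 did not; of the counts of list members 33 moved by over 1.5 times, 14 of them at the 99th percentile, and 147 did not. The cause was not tested.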

Other observations

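The tests on gene length, on the spread of the imprinted list and on the chromosome 7 neighbours were chosen after the results were seen. Some gene families outside the fixed lists had median differences outside the range of random lists, by small amounts. The families were picked by symbol after the data were seen and were compared with random lists matched on signal. Of 228 Zfp zinc finger genes above background, 168 were higher in clone 2 and 58 in clone 1, with a median of 0.16 (percentile 99.7); of all genes above background 63.2% were higher in clone 2. The medians of proteasome subunits (-0.06, percentile 0.21), mitochondrial ribosomal proteins (-0.015, percentile 0.635) and respiratory chain complex I (-0.03, percentile 1.71) lay low, while their members went both ways, with 15, 35 and 19 genes higher in clone 2 and 22, 40 and 23 in clone 1. Centring, which adds the same amount to every gene, sets the mitochondrial ribosomal proteins at 0.015 and complex I at 0, so what is given is their place relative to other genes and not a sign. Relative to random lists these 3 families and the Zfp genes lay outside the range under quantile and loess normalization too. The offsets are of the size of the trend with gene length, whose medians were 0.03, 0.09 and 0.13 in the 3 bins from short to long genes. Among random lists matched on length as well as signal, the mitochondrial ribosomal proteins (percentile 9.27) and complex I (percentile 5.96) lay inside the range, and the proteasome subunits (percentile 0.205), Zfp genes (percentile 99.8) and keratins (percentile 0.11) outside it. Cytosolic ribosomal proteins (46 genes, median 0.015, percentile 32.5), solute carriers (183 genes, 0.09, percentile 46.2), Rbm RNA-binding proteins (32 genes, 0.12, percentile 74.1) and Rnf ring finger proteins (55 genes, 0.10, percentile 56.4) lay within the random range; the medians of solute carriers and Rnf proteins fell below 0 under quantile normalization. Of 8 keratin genes above background 6 were lower in clone 2 (median -0.26, percentile 0.03), as were 4 of 4 Hox genes (median -0.27, percentile 2.83, inside the range, but outside it under quantile normalization at percentile 2.13). The last 2 families stayed negative under each normalization.

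The mean absolute difference of the 21 imprinted genes above background was 0.468, above every one of the random lists matched on signal (percentile 100, upper end of the random range 0.305), and 5 of the 29 lists passed their own upper end; with 1 array per clone no value measures array noise, which stays open. The excess rests on 6 genes of 2 linked clusters, Meg3, Rian and Mirg and Cdkn1c, Phlda2 and Igf2: the other 15 had 0.234 (percentile 64.8, upper end 0.317), and the random lists treat linked neighbours as independent genes. A gain or loss of the wider regions is argued against by their neighbours, each read by its brightest probe set. The 15 other genes within 1.5 Mb of Meg3 had a median of 0.04 (standard error 0.088, Evl the highest at 1.02). On the same measure Meg3 differed by 0.57, Rian by 0.88 and Mirg by 0.64. The 7 probe sets of these 3 genes above background in both clones had a median of 0.88. These 15 lie to either side of the cluster, none between Dlk1 and Mirg. They leave out Dlk1 itself (0.32), above background in clone 2 alone. With Dlk1 the median of 16 genes was 0.04 (standard error 0.084). On chromosome 7, 13 other genes within 1 Mb of the span from Igf2 to Phlda2 had a median of -0.02 (standard error 0.076, from -0.33 to 0.53). These 13 leave out 6 genes of the imprinted cluster, Tspan32 (-0.67), Slc22a18 (-0.53), Ascl2 (-0.31), Tssc4 (-0.16), Nap1l4 (-0.02) and Kcnq1ot1 (0.37); with them the median of 19 genes was -0.03 (standard error 0.084). A copy change confined to the chromosome 12 cluster, or to part of either cluster, and a difference between cultures stay open. Cdkn1c, Phlda2 and Igf2 rest on 1 probe set above background each, and no biological explanation was tested.

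The excess of probe sets 2-fold higher in clone 2, 111 against 19 by measured signals or a ratio of 5.84, was weighed against the scale of the arrays, single probe sets and gene length. The ratio was 3.68 after the signal-dependent trend was removed by loess and 5.11 with the higher background asked of both clones, which argues against that trend or the unequal levels as the whole cause; it was 2.92 under quantile normalization, 2.44 with background at the 90th percentile and 0.572 with no filter, so the excess holds for probe sets above background and its size depends on both choices. The reading of single probe sets stays open, since 73.3% of 15 second probe sets matched in direction, between the limits of 60% and 80% set for and against it, and the normalizations gave 50.0% to 81.2%, which crosses both. The test could not decide it, because the limit of 60% lies below the 63.2% of genes above background that were higher in clone 2. Gene length went with the excess at 1 probe set per gene, where 39 genes in all were 2-fold higher in clone 2 and 12 in clone 1. In the shortest of 3 equal bins of genomic span 8 genes were 2-fold higher in clone 2 and 7 in clone 1 (ratio 1.14), in the middle bin 11 and 3, and in the longest 20 and 1. The median difference in these bins was 0.03, 0.09 and 0.13. Probe sets other than a gene's brightest, or without a single symbol, did not enter these counts. A bias with gene length is therefore a candidate explanation; RNA quality per clone was not analysed here, and no biological explanation was tested.

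Among Y-linked genes chosen after their values were seen, Uty and Kdm5d were not above background in either clone.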
